A study of Mus musculus with 10 samples.

How the data were processed

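RNA was measured in 10 libraries from sorted mouse bone marrow lymphoid progenitors of 3 populations, called ALP (n = 2), BLP (n = 3) and hCD25 (n = 5) in the labels. Per the labels, total RNA was extracted with a column kit for small samples and the libraries were made with Nugen kits that amplify cDNA. Per the submitters' processing notes, FastQC, HISAT and DESeq were used with genome build mm10. The notes give no versions and do not say what each tool was used for. The counting tool and its annotation are not given in the sources used here.

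The deposited files hold counts per gene symbol, 1 file per library, with 43280 gene rows each. The values were checked to be whole numbers with totals that differ between libraries, so the authors deposited raw counts with no normalization. Gene symbols were matched to GENCODE M21, on the same build, for coordinates and gene classes only. A total of 39379 symbols matched 1 annotated gene. Of the 325 symbols in the gene lists, 4 were found under an older symbol and Iglc1 had no row.

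Differences between populations were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group, with a minimum count of 10 and a minimum total count of 15, which left 17179 genes. TMM factors scaled the libraries, and counts per 1e6 counts (CPM) are given on the TMM-scaled library size. A model with 1 mean per population was fitted to all 10 libraries, because ALP has 2 libraries and the spread has to be shared. The quasi-likelihood test gave p-values, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Means of CPM are given with their SD over libraries. All tests were two-sided.

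There were 22 gene lists and a rule for the genes to be named, fixed before the data were examined. Lists were tested with camera from limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The rule for named genes took the sort markers with Il2ra and Ptcra, and the 10 largest rises and the 10 largest falls among genes past the threshold. The latter needed a mean of at least 10 CPM in the higher population and CPM ranges that did not overlap, and predicted gene models and non-coding classes were left out. The rule also took up to 3 passing members per direction from each list, and the 2 most abundant members of a list with fewer than 2 passing members. Ptcra was below the count filter. AL603913.1, a clone-based name, was kept because the rule did not exclude it. Genes outside the rule are Cd27, Cd44, Cd79b, Chchd10, Gimap4, Gbp8, Hes1, Hlf, Ighm, Mycn, Mzb1, Vpreb2, 6330403A02Rik and Gm19980. Also outside it are Pax5, Vpreb1 and Vpreb3 for hCD25 against ALP and Ebf1 and Gfra2 for hCD25 against BLP. All of these were chosen after their values were seen.

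Where a population had 0 counts of a gene, the fold is a lower bound against 3 counts over the whole population. With 1 to 3 counts, the ratio of CPM is given with its exact Poisson interval at 95%. These bounds and intervals cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Total counts per library ran from 4.84 to 36.1 in units of 1e6 counts, so that 3 counts in 1 library correspond to between 0.0831 and 0.62 CPM.

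The procedure was tested on simulated data built from these libraries. With the dispersions estimated from the data, edgeR recovered 9.09% of the genes changed 8-fold for BLP against ALP, 16.7% for hCD25 against ALP and 31.8% for hCD25 against BLP, and 0% of those changed 2-fold in each. With a dispersion of 0.05 for every gene, it recovered 95.5%, 97.0% and 97.0% of the 8-fold changes in the same order. Of the genes DESeq2 called in the simulation with estimated dispersions, 65.2%, 67.5% and 55.3% were genes that had not been changed, against 0%, 8.33% and 6.90% for edgeR. The edgeR shares stand for 0, 1 and 2 genes. For limma-voom the shares were 10%, 0% and 3.85%. The estimated dispersions were those of edgeR itself. With a dispersion of 0.05 the shares were 10.65%, 12.7% and 7.19% for DESeq2, against 2.63%, 8.98% and 3.09% for edgeR. Camera called the changed list in each of the 3 simulated comparisons with estimated dispersions, and of the 21 unchanged lists it called 0, 1 and 0. Genes were simulated independently of each other and without a batch. The simulation therefore cannot show how often camera calls unchanged lists whose genes vary together.

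The deposited files follow 2 naming styles, which were treated as a possible library batch. ALP 1 and 2 and BLP 1 and 2 share the first style, and BLP 3 and the 5 hCD25 libraries share the second. ALP and hCD25 share no style, so BLP alone links them. Alternatives planned before the data were examined were RLE size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no count filter, a filter of 5 CPM in 2 libraries, a fit of only the 2 populations compared, the replicate number as a block, the naming style as a term, comparisons within 1 style, hCD25 libraries 4 and 5 summed because their file names share a number, and leaving out each library in turn. Alternatives added after seeing the data were leaving out genes on X and Y, the style term without BLP 2, and robust empirical Bayes estimation. A test of falls beyond 1 on the log2 scale (edgeR's glmTreat over all genes) was added after seeing the data. Within the second style BLP has 1 library, so the spread there is that of hCD25 alone. Left out of the comparisons were only genes below the filter.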

Results

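To compare the transcriptomes of early lymphoid compartments of mouse bone marrow, RNA sequencing counts of 3 progenitor populations from C57BL/6 mice with a wild-type label were analysed. All 3 were sorted for Sca1, Kit, IL7r and Flt3 and against lineage markers and CD19. ALP (n = 2) and BLP (n = 3), in the usual terms all-lymphoid and B cell-biased lymphoid progenitors, were also sorted against B220 and Lpam1, and differ in the surface protein Ly6D, absent in ALP and present in BLP. The hCD25 population (n = 5) was sorted for hCD25, and its gate names no criterion for B220, Lpam1 or Ly6D. The files of hCD25 4 and 5 share a number in their names, so these libraries may not be independent. The labels do not say what hCD25 is or what drives it, so a difference in mouse line from the other populations stays open. Nor do they give the sex of the mice or whether replicates are separate mice. The p-values therefore measure the spread between these samples, which may be technical.

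In units of 1e6 counts, the ALP libraries held 32.9 and 36.1, the BLP libraries 29.2, 14.98 and 8.80, and the hCD25 libraries 5.36, 11.4, 8.79, 4.89 and 4.84. BLP 2 stood apart, with 13804 genes detected against 16415 to 21100 in the others, and a median Spearman correlation of 0.724 with the other libraries, across genes, against 0.819 to 0.880. Libraries also differed by file naming style. The ratio of counts of the gene model Gm28661 to mt-Co2 was 0.653 to 0.921 in ALP 1 and 2 and BLP 1 and 2, and 0.994 to 1 in BLP 3 and the hCD25 libraries. The Spearman correlation of BLP 3 across genes was 0.874 with BLP 1, 0.730 with BLP 2 and 0.839 to 0.904 with the hCD25 libraries, while that of BLP 1 was 0.952 and 0.956 with ALP 1 and 2. The second principal component, 20.2% of the variance, held ALP 1, ALP 2 and BLP 1 at 120.3, 114 and 109.5, BLP 3 at 11.15, BLP 2 at -33.9 and the hCD25 libraries at -124.5 to -28.7. The first principal component held 38.9% of the variance and separated BLP 2 from the rest. The biological coefficient of variation was 0.833, and the median standard error of a log2 fold change was 1.1 for BLP against ALP, 0.978 for hCD25 against ALP and 0.855 for hCD25 against BLP.

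The first comparison asked how the Ly6D-positive BLP differ from the Ly6D-negative ALP. Of 24 tested B lineage genes 4 rose in BLP by edgeR, as did Ly6d and Gfra2. Ebf1, a transcription factor needed for B cell specification, rose from 8.44 ± 0.0213 CPM (SD, n = 2) in ALP to 132 ± 53.3 CPM (SD, n = 3) in BLP, a log2 fold change of 3.96 ± 0.53 (SE). Rag1, a component of the V(D)J recombinase, rose from 29.3 ± 3.94 to 278 ± 154 CPM, a log2 fold change of 3.24 ± 0.45. Cd79a, which encodes a signalling chain of the B cell receptor, rose by a log2 of 7.21 ± 0.88 to 9.65 ± 7.31 CPM, and Pou2af1, a transcriptional coactivator of B cells, rose by a log2 of 6.38 ± 0.71 to 14.9 ± 8.30 CPM. Ly6d itself was 0.114 ± 0.0445 CPM in ALP and 60.3 ± 46.6 CPM in BLP, and Gfra2, a co-receptor for neurturin, was at 2 counts in ALP and 17.3 ± 9.02 CPM in BLP, a ratio of 609 with a counting interval of 169 to 5030.

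By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8 of 17179 genes changed, all 8 higher in BLP. The adjusted p was 0.000845 for Gfra2, 0.00111 for Ly6d, 0.00138 for Pou2af1, 0.00364 for Cd79a, 0.00901 for Ebf1 and 0.0108 for Rag1. The other 2 were the gene models Gm19980, at a log2 of 6.18, and 6330403A02Rik, at 5.85. At an unadjusted p under 0.05 there were 808 genes, 709 higher and 99 lower, where 859 are expected by chance. No gene fell by edgeR, and 3 were lower by DESeq2 and 0 by limma-voom. The count of 8 was 1 without ALP 1, where Gfra2 alone stayed past the threshold among these genes, 5 without ALP 2 and 22 without BLP 2. Without ALP 1 the log2 fold change stayed close while calls were lost: 8.59 for Ly6d (adjusted p = 0.0891), 5.77 for Pou2af1 (0.0918), 6.63 for Cd79a (0.209), 3.96 for Ebf1 (0.419) and 3.10 for Rag1 (0.657). Without ALP 2 it was 8.02 for Cd79a (0.0851), 3.95 for Ebf1 (0.362) and 3.38 for Rag1 (0.362). The count was 8 with naming style as a term. By edgeR it was 0 when only ALP and BLP were fitted and 0 within the first naming style, where the log2 fold change was 4.06 for Ebf1, 8.23 for Ly6d and 6.59 for Cd79a.

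Of the 24 tested members of the B lineage list, 4 rose between ALP and BLP, 0 fell and 20 did not pass, and 9 rose when adjusted over the list alone, 8 by DESeq2 and 4 by limma-voom. The median log2 fold change was 1.62, 23 of 24 members were positive, and the list passed camera with an adjusted p of 3.57e-14. Of the 19 tested members of the T lineage list, 0 passed by edgeR, 1 when adjusted over the list alone, 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom, and camera gave an adjusted p of 0.231. Notch1, the receptor that directs T cell fate, was 318 ± 38.5 CPM in ALP and 438 ± 136 CPM in BLP. Sorting receptors common to both gates did not pass: the log2 fold change was 0.62 ± 0.32 for Il7r, 0.33 ± 0.36 for Flt3 and -0.34 ± 0.41 for Kit. Dntt, the terminal transferase of V(D)J joining, was 2108 ± 45.0 CPM in ALP and 2577 ± 200 CPM in BLP, with a log2 of 0.29 ± 0.26. Myc, at 0.31 ± 0.35, and Mpo, the myeloid peroxidase, at 0.24 ± 0.76, did not pass either.

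**Figure D1:**
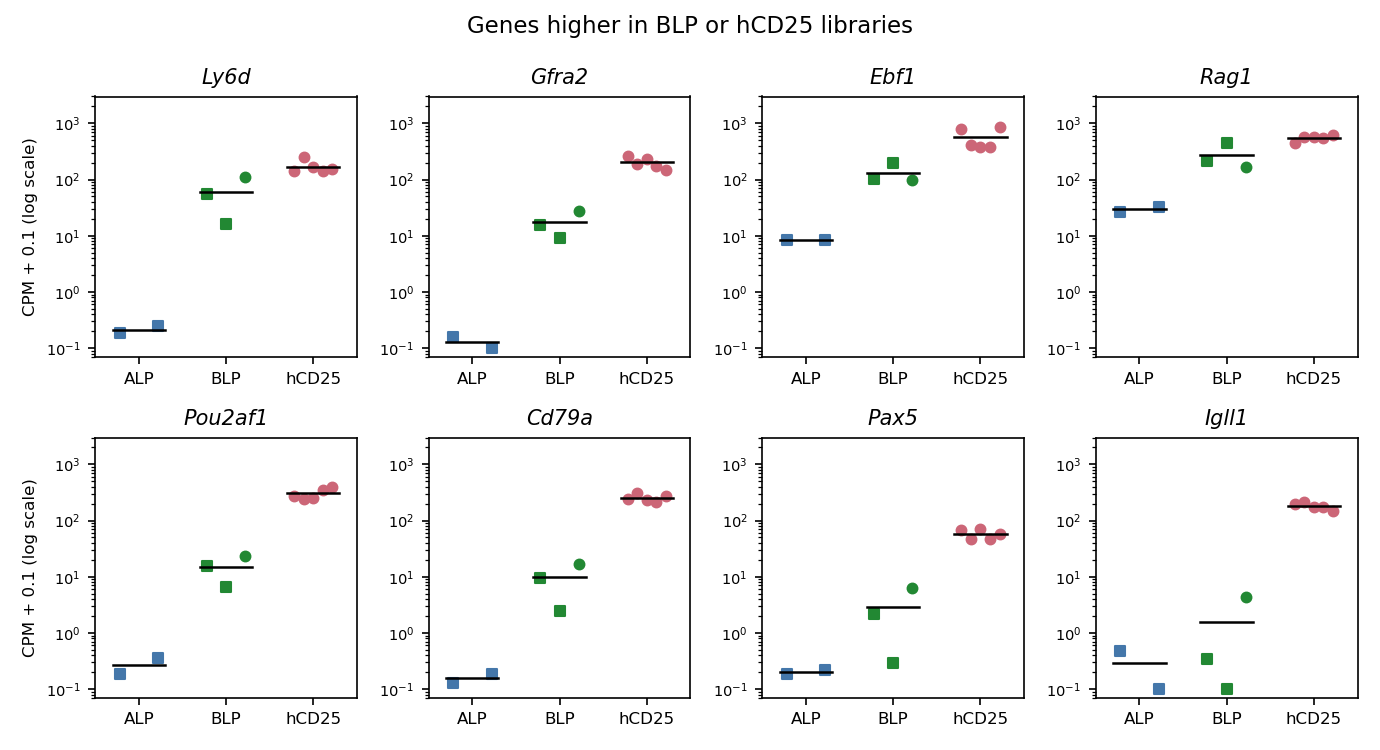
CPM plus 0.1 (log axis) of 8 genes in each library of ALP (n = 2), BLP (n = 3) and hCD25 (n = 5), with squares for the first file naming style, circles for the second and black lines for the mean. Pou2af1 averaged 0.173 CPM in ALP, 14.9 CPM in BLP and 304 CPM in hCD25, and Igll1 was at 149 to 212 CPM in the hCD25 libraries and at most 4.22 CPM elsewhere.

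The second comparison set hCD25 cells against ALP. Of 24 tested B lineage genes 13 rose in hCD25 by edgeR, while others such as Cd79b and Ighm did not pass. Pax5, the commitment factor of the B lineage, rose from 0.0998 ± 0.0239 CPM (SD, n = 2) in ALP to 58.1 ± 11.7 CPM (SD, n = 5) in hCD25, a log2 fold change of 9.08 ± 1.30 (SE). Igll1, which encodes the lambda5 part of the surrogate light chain, rose from 0.194 ± 0.274 to 183 ± 24.8 CPM, and Vpreb1, its partner, from 0.649 ± 0.5264 to 152 ± 46.0 CPM. Ebf1 rose to 568 ± 241 CPM, Cd79a to 256 ± 39.6 CPM, Pou2af1 to 304 ± 68.7 CPM and Rag1 to 550 ± 65.6 CPM. Cd19 was 38.3 ± 14.2 CPM in hCD25 and 0.363 ± 0.307 CPM in ALP, although both gates exclude CD19 protein. In the other direction Cd34, a marker of early progenitors, fell from 339 ± 1.17 to 33.9 ± 12.6 CPM, a log2 of -3.32 ± 0.35, and Bcl2, a survival gene, fell from 240 ± 19.3 to 51.2 ± 8.86 CPM, a log2 of -2.23 ± 0.30.

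By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 67 genes changed, 43 higher and 24 lower in hCD25 than in ALP, with 2060 (1226 higher, 834 lower) at an unadjusted p under 0.05 where 859 are expected by chance. DESeq2 called 904 higher and 226 lower, and limma-voom 1900 and 2119. Among the largest rises, Gfra2 reached 202 ± 48.4 CPM (adjusted p = 2.47e-05), a ratio of 7124 with a counting interval of 1972 to 58820. Ly6d reached 170 ± 45.2 CPM (adjusted p = 0.000144). Agpat9 and Trem1 had 0 counts in ALP and were at least 1050-fold and at least 961-fold higher in hCD25, at 44.7 ± 23.1 and 40.9 ± 9.85 CPM. Sell, the homing receptor L-selectin, rose by a log2 of 2.18 ± 0.31 to 1029 ± 183 CPM. Falls included Slc35d3 (log2 -5.20 ± 0.49), Epha7 (with 2 counts in hCD25, a ratio of 242.5 with a counting interval of 67.1 to 2002), Gcnt2 (-4.83 ± 0.92), Csf3r, the receptor for G-CSF (-4.11 ± 0.79), Ctr9 (-2.79 ± 0.36) and Itih5 (-2.46 ± 0.43). The guanylate-binding protein genes Gbp4 (-4.17 ± 0.61), Gbp6 (-3.20 ± 0.39) and Gbp11 (-4.87 ± 0.96) fell too. Of these falls, Slc35d3, Ctr9 and Gbp6 kept their call in all 10 fits that left out 1 library, and Gbp4 in 8. Gcnt2 kept it in 5, Csf3r and Itih5 in 4, and Epha7 and Gbp11 in 3. The clone-based gene AL603913.1 rose by 9.70. Within mitochondrial genes, mt-Nd3 rose by a log2 of 6.00 ± 0.91 and mt-Nd6 changed by -3.34 ± 0.62.

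Of the 24 tested B lineage genes, 13 rose between ALP and hCD25, 0 fell and 11 did not pass, and 20 rose when adjusted over the list alone, 19 by DESeq2 and 21 by limma-voom. The median log2 was 4.77 and the list passed camera with an adjusted p of 1.39e-32. Of the 18 tested genes of stem and multipotent progenitors, Cd34 alone fell, 0 rose and 17 did not pass, and 5 fell when adjusted over the list alone, among them Mycn (log2 -4.00 ± 0.81) and Hlf (-3.25 ± 0.99). The median was -1.54 and the list passed camera with an adjusted p of 2.59e-06. Of the 19 T lineage genes 0 passed by edgeR, with 3 higher and 3 lower at an unadjusted p under 0.05, 2 higher and 1 lower by DESeq2, 2 higher and 3 lower by limma-voom, and 1 higher and 2 lower when adjusted over the list alone. Camera gave an adjusted p of 0.797 for the T lineage list, whose median was -0.04 and whose mean was 0.42. The T lineage member higher over the list alone was Hes1, a target of Notch signals, at 19.7 ± 5.07 CPM in hCD25 and 0.294 ± 0.21 CPM in ALP. Kit (-0.81 ± 0.37), Flt3 (-0.91 ± 0.31), Il7r (0.15 ± 0.29), Notch1 (-0.68 ± 0.33), Dntt (-0.17 ± 0.24), Myc (-0.75 ± 0.31), Mpo (-1.50 ± 0.65) and Il2ra, the mouse CD25 gene (2.62 ± 2.32), did not pass by edgeR. DESeq2 called none of these, and limma-voom called Kit, Flt3, Notch1, Myc and Mpo lower.

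ALP and hCD25 share no naming style, so style and population cannot be told apart without BLP. With style as a term, which rests on BLP 3, 10 genes were called, all higher in hCD25, among them Gfra2, Cd79a, Pou2af1, Ebf1, Ly6d, Rag1 and Chchd10. The B lineage list then had an adjusted p of 1.14e-28, and the log2 fold change was 11.33 for Gfra2, 6.65 for Ebf1 and -3.47 for Cd34 (adjusted p = 0.187). Some other named genes had smaller values with this term and lost their calls, among them Igll1 at 5.16 (0.991), Pax5 at 6.72 (0.512), Vpreb1 at 6.17 (0.991) and Trem1 at 9.05 (0.991). Others, such as Gbp4 at -4.69 (0.72) and Agpat9 at 12.46 (0.916), lost theirs with values no smaller than in the full fit. The count of 67 was 17 without ALP 1, 14 without ALP 2, 315 without BLP 1, 799 without BLP 2, 558 without BLP 3, and 37, 39, 38 and 39 without hCD25 1, 2, 4 and 5. It was 45 with hCD25 4 and 5 summed. Of 34 named genes that passed, 11 passed without each library in turn, namely the 7 just given and Cd34, Ctr9, Gbp6 and Slc35d3. Pax5 was at a log2 of 8.84 (adjusted p = 0.211) without ALP 1 and 9.29 (0.152) without ALP 2, Vpreb1 at 7.195 (0.291) and 9.05 (0.145), Bcl2 at -2.32 (0.068) and -2.15 (0.120), and Igll1, whose call was also lost without hCD25 1, 2, 4 or 5, at 14.24 (0.106) and 8.84 (0.283). Cd19 passed in no fit that left out an ALP or hCD25 library, and was at 7.935 (0.360) without ALP 1.

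The third comparison set hCD25 cells against BLP, which both carry Ly6d transcripts. Of 24 tested B lineage genes 8 rose in hCD25 by edgeR, while others such as Vpreb2, Cd79b and Ighm did not pass. Igll1 rose from 1.49 ± 2.37 CPM (SD, n = 3) in BLP to 183 ± 24.8 CPM (SD, n = 5) in hCD25, a log2 fold change of 7.03 ± 1.22 (SE), Vpreb1 rose by 6.11 ± 0.96 and Vpreb3 by 5.03 ± 0.84. Cd79a rose from 9.65 ± 7.31 to 256 ± 39.6 CPM, a log2 of 4.73 ± 0.58, Pou2af1 rose by 4.34 ± 0.49, Pax5 by 4.36 ± 0.84, Ebf1 by 2.10 ± 0.39 and Gfra2 by 3.55 ± 0.48. Cd34 fell from 254 ± 15.6 to 33.9 ± 12.6 CPM, a log2 of -2.90 ± 0.33, and Bcl2 fell from 214 ± 53.5 to 51.2 ± 8.86 CPM. The lymphoid transcription factor Ikzf1 fell from 917 ± 361 to 367 ± 36.5 CPM, a log2 of -1.32, which was -0.951 without BLP 2. Ly6d did not pass, at a log2 of 1.49 ± 0.50 (adjusted p = 0.181 by edgeR), nor did Rag1 at 0.99 ± 0.32.

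By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 51 genes changed, 23 higher and 28 lower in hCD25 than in BLP, with 2747 (815 higher, 1932 lower) at an unadjusted p under 0.05 where 859 are expected by chance. The balance of directions depended on the fit. It was 82 higher and 398 lower with no count filter, 16 and 45 without BLP 1, and 45 and 28 without BLP 2. DESeq2 gave 325 and 460, and limma-voom 291 and 181. The adjusted p was 0.00108 for Pou2af1 and for Cd34, 0.00214 for Cd79a, 0.0041 for Bcl2, 0.0286 for Igll1 and 0.0481 for Pax5. Cd24a rose by a log2 of 1.95 ± 0.25, Sell by 1.53 ± 0.25, mt-Nd3 by 4.26 ± 0.68, and Hspa1a, a stress-induced chaperone, by 8.43 ± 1.47. Falls included Slc35d3 (-4.89 ± 0.47), Il17re (-5.71 ± 1.1), Psd3 (-3.15 ± 0.56), Runx2 (-2.11 ± 0.40), Gbp4 (-3.96 ± 0.58), Gbp6 (-3.28 ± 0.37), Gbp9 (-4.10 ± 0.74) and Gbp11 (-5.11 ± 0.92). The calls of Slc35d3, Gbp4 and Gbp6 held in all 10 fits that left out 1 library. Those of Il17re, Psd3, Gbp9 and Gbp11 held in 2 and that of Runx2 in 1. Without BLP 2, 5 of the 32 named genes that passed lost their calls, all of them falls. The log2 was then -3.515 for Il17re (edgeR adjusted p = 0.189), -3.33 for Gbp9 (0.0617), -1.98 for Psd3 (0.0745), -1.37 for Runx2 (0.0996) and -0.951 for Ikzf1 (0.0898). Clu had 1 count in hCD25 and 15.4 ± 10.4 CPM in BLP, a ratio of 564 with a counting interval of 101.2 to 22280.

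Of the 24 tested B lineage genes, 8 rose between BLP and hCD25, 0 fell and 16 did not pass, and 18 rose when adjusted over the list alone, 14 by DESeq2 and 15 by limma-voom. The median log2 was 3.03 and camera gave an adjusted p of 1.39e-16. In all, 21 of the 24 had mean CPM in the order ALP, BLP, hCD25 from low to high, against 19.3% of all genes. Of the 18 stem and multipotent progenitor genes, Cd34 alone fell, 0 rose and 17 did not pass, and 7 fell when adjusted over the list alone. Their median was -1.17 and camera gave an adjusted p of 0.00343, which was adjusted p = 0.0649 with an estimated correlation. Of the T lineage genes 0 passed by edgeR, with 2 higher and 6 lower at an unadjusted p under 0.05, 2 lower by DESeq2, 1 lower by limma-voom and 2 lower when adjusted over the list alone, and camera gave an adjusted p of 0.182. Values that did not pass by edgeR were Cd19 (4.58 ± 0.95), Flt3 (-1.24 ± 0.28), Notch1 (-1.14 ± 0.29), Myc (-1.05 ± 0.27), Mpo (-1.74 ± 0.59), Mycn (-3.39 ± 0.76), Hlf (-1.02 ± 0.91), Il7r (-0.47 ± 0.25), Kit (-0.46 ± 0.33), Dntt (-0.46 ± 0.21) and Il2ra (4.98 ± 2.302). Of these, DESeq2 and limma-voom both called Cd19 higher and Flt3, Notch1 and Mycn lower, DESeq2 alone called Myc lower, and limma-voom alone Mpo.

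The count of 51 was 1, the fall of Slc35d3, with style as a term, and 11, all higher in hCD25, within the second style. That last count is no test of BLP, because BLP 3 is its only BLP library and the spread comes from the hCD25 libraries alone. The log2 differences to BLP 3 there were in the direction of the full fit for the named genes that passed, among them Igll1 (5.435), Vpreb1 (5.17), Vpreb3 (4.06), Cd79a (3.91), Pou2af1 (3.73), Chchd10 (2.805), Pax5 (3.22), Ebf1 (2.52), Cd34 (-2.995), Bcl2 (-1.67), Runx2 (-0.77) and Ikzf1 (-0.84). That direction was fixed beforehand, because the CPM ranges of hCD25 and BLP did not overlap for any called gene. The shared direction is therefore no check on a batch. With style as a term the B lineage list had an adjusted p of 1.75e-26 by camera with the preset correlation. Only BLP holds both styles, so that fit in effect sets hCD25 against BLP 3. It too rests on 1 BLP library. The count was 1308 without BLP 3, and 27, 26, 28 and 27 without hCD25 1, 2, 4 and 5. It was 32 with hCD25 4 and 5 summed. Of 32 named genes that passed in the full fit, 16 passed without each library in turn, among them Cd79a, Pou2af1, Gfra2, Cd34, Bcl2 and Slc35d3. Igll1 was at a log2 of 6.95 (adjusted p = 0.0932) and Vpreb1 at 5.92 (0.0543) without hCD25 2, Vpreb3 at 5.01 (0.0679) without hCD25 5, Pax5 at 4.33 (0.127) and Ebf1 at 2.01 (0.0945) without hCD25 1, and Ikzf1 at -1.27 (0.176) without hCD25 4. These are single examples. Over the 10 fits that left out 1 library, the calls of Pax5, Ebf1 and Ikzf1 held in 2. Those of Igll1 and Vpreb3 held in 4 and that of Vpreb1 in 8.

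Sex-linked genes differed with the populations. Ddx3y, encoded on Y, had 0 counts in ALP and in BLP and 25.33 ± 12.95 CPM in hCD25, at least 595-fold higher than in ALP and at least 412-fold higher than in BLP. Eif2s3y, Kdm5d and Uty rose by a log2 of 8.92 ± 1.04, 8.42 ± 0.80 and 6.80 ± 1.01 against BLP, and Eif2s3y by 10.07 against ALP. Xist, the RNA of the inactive X, fell from 13410 ± 7236 CPM in BLP to 1739 ± 994 CPM in hCD25, a log2 of -2.95 ± 0.42. BLP 1, 2 and 3 were at 9695, 21750 and 8787 CPM, and the fall against ALP was smaller, at -2.32 ± 0.45. Each hCD25 library carried Xist, at 777 to 3349 CPM, as well as Y-linked transcripts, so the values do not settle the sex behind these libraries. Genes on X and Y made up 8 of the 67 genes called against ALP and 9 of the 51 called against BLP.

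**Figure D2:**
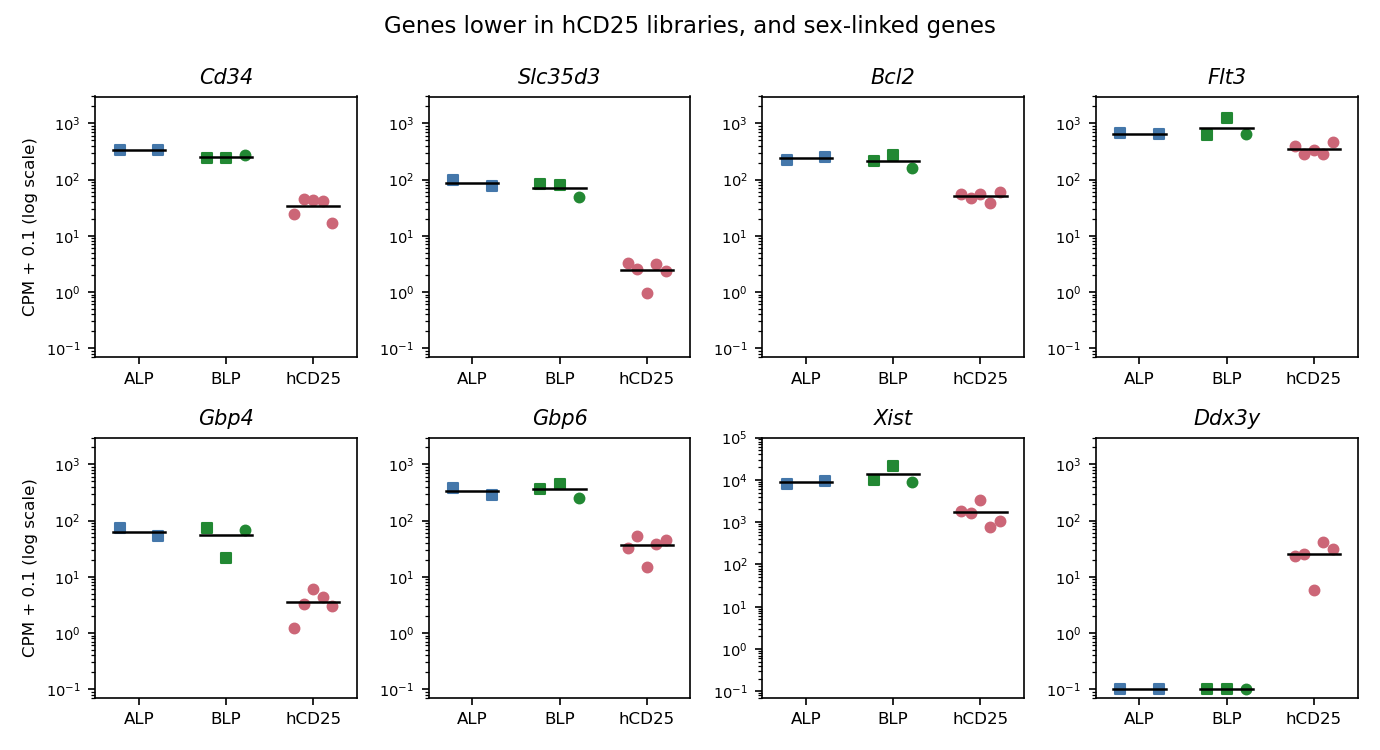
CPM plus 0.1 (log axis, wider for Xist) of 8 genes in each library of ALP (n = 2), BLP (n = 3) and hCD25 (n = 5), with squares for the first file naming style, circles for the second and black lines for the mean. Cd34 averaged 339 CPM in ALP, 254 CPM in BLP and 33.9 CPM in hCD25, and Flt3, which did not pass the test, 658, 829 and 351 CPM.

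Markers of other cells varied between libraries. The summed CPM of the mature neutrophil list was 0.166 and 88.8 in ALP, 1.197, 0.395 and 317 in BLP, and 31.5, 278, 1240, 384 and 4.93 in hCD25 1 to 5. Haemoglobin genes summed to 508 CPM in hCD25 3 and to at most 220 CPM in the others. The macrophage and monocyte list had a camera adjusted p of 0.182 to 0.546 over the 3 comparisons, the mature neutrophil list 0.0565 to 0.684, and the erythroid and megakaryocyte list 0.198 to 0.713. The range was 0.0674 to 0.614 for myeloid progenitor genes, 0.182 to 0.524 for plasmacytoid and 0.262 to 0.980 for conventional dendritic genes, 0.162 to 0.623 for mature B and plasma cells, 0.609 to 0.898 for NK and cytotoxic genes, and 0.130 to 0.427 for innate lymphoid genes.

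The remaining lists did not pass camera in any of the 3 comparisons either. Their adjusted p ranged from 0.0516 to 0.555 for the sort markers, 0.0741 to 0.726 for Notch targets, 0.0516 to 0.537 for V(D)J recombination, 0.126 to 0.382 for the cell cycle, 0.609 to 0.974 for IL-7 receptor and STAT5 genes, 0.0674 to 0.496 for immediate early and stress genes, 0.0565 to 0.614 for the interferon response, 0.0741 to 0.974 for E protein and Id genes, 0.0741 to 0.898 for trafficking receptors and 0.0649 to 0.837 for mitochondria-encoded genes. Fry, which tests a list against no change and not against other genes, passed some of these lists. Its adjusted p was 0.0193 (BLP against ALP) and 0.00723 (hCD25 against ALP) for the sort markers, 0.0193 and 0.0198 for V(D)J recombination, 0.0315 for Notch targets in hCD25 against ALP and 0.00501 for the cell cycle in hCD25 against BLP, each higher in the first population. The sort markers hold Ly6d, by which BLP and ALP were gated and which alone was called there, so that pass follows the gate. For hCD25 against ALP the median log2 of the sort markers was -0.225, with 4 of 9 positive and Ly6d and Cd19 alone called. The stem and multipotent list in BLP against ALP was lower by fry, at 0.0247, and did not pass camera, at 0.0649. The B lineage list passed fry at 0.0379 for BLP against ALP, 2.27e-05 for hCD25 against ALP and 0.000208 for hCD25 against BLP. In at least 1 comparison the median, the mean and the direction of the test differed in sign for the sort markers and for the T lineage, innate lymphoid, NK, mature B and plasma, IL-7 receptor, E protein, trafficking and mitochondrial lists. With an estimated correlation the camera calls of the B lineage list held, with adjusted p of 0.0234 for BLP against ALP, 0.00176 for hCD25 against ALP and 0.0147 for hCD25 against BLP, as did the stem and multipotent list for hCD25 against ALP at 0.00904.

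**Figure D3:**
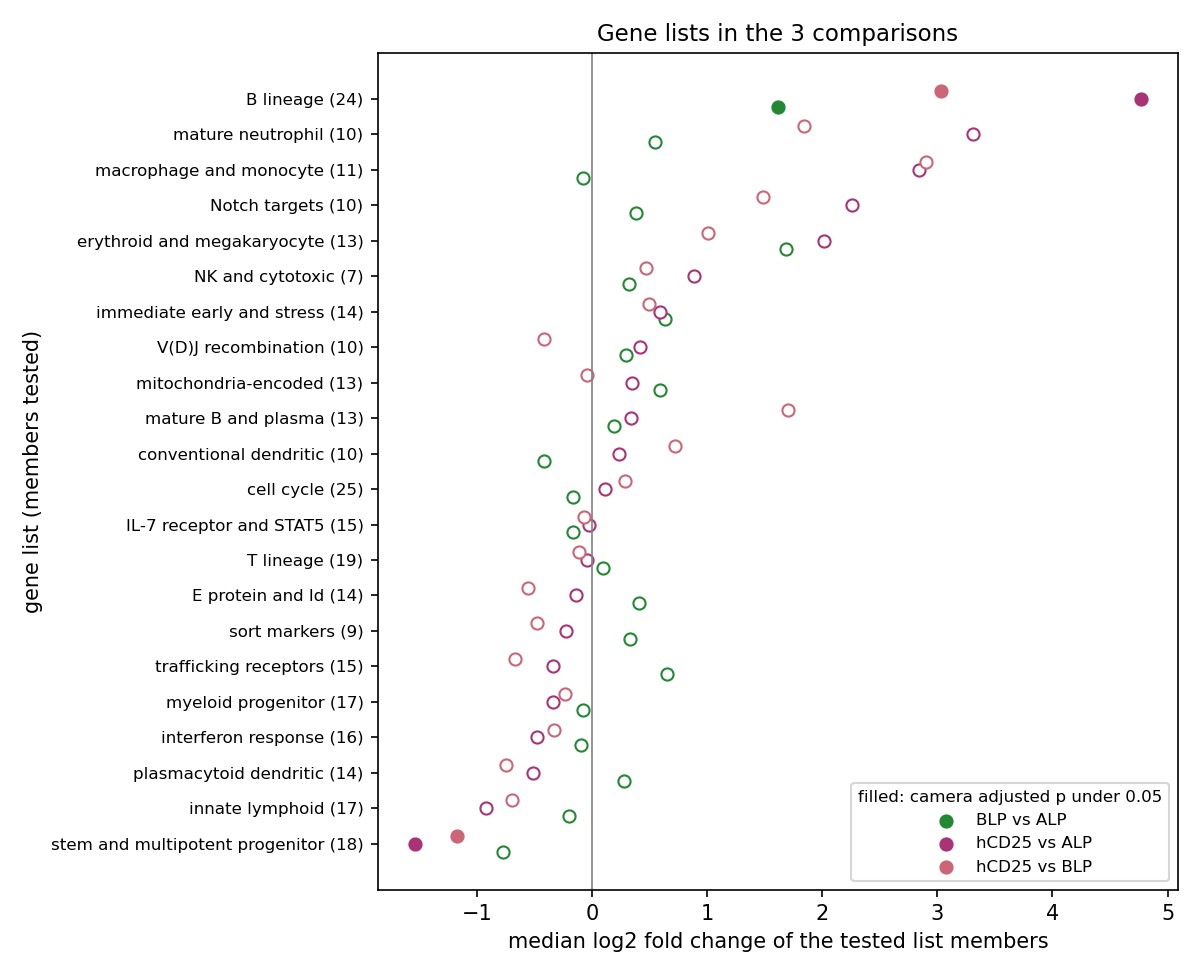
Median log2 fold change (horizontal axis) of the tested members of each of the 22 gene lists in the 3 comparisons, first population over second, with filled points where the camera adjusted p with the preset correlation was under 0.05. The B lineage list lies at 1.62, 4.77 and 3.03 and the stem and multipotent list at -0.77, -1.54 and -1.17 for BLP against ALP, hCD25 against ALP and hCD25 against BLP, the first of the latter open.

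On build mm10 with GENCODE M21, the protein-coding genes that led these comparisons lie on chromosome 15 from 74762056 to 74763620 (Ly6d), 14 from 70890120 to 70979838 (Gfra2), 11 from 44617317 to 45008091 (Ebf1), 2 from 101638282 to 101649501 (Rag1), 9 from 51213708 to 51240080 (Pou2af1) and 7 from 24897381 to 24902197 (Cd79a). Igll1 lies on chromosome 16 from 16860671 to 16863985, Pax5 on 4 from 44524757 to 44710487, Cd34 on 1 from 194938819 to 194961279, Bcl2 on 1 from 106538178 to 106714274 and Slc35d3 on 10 from 19847916 to 19851459. Exons of Gbp4, Gbp8 and Gbp9 overlap on the same strand of chromosome 5, so that a read there can fall in more than 1 of them, and Gbp11 is annotated as a polymorphic pseudogene. Exons of mt-Nd6 and mt-Nd5 overlap on opposite strands, and it is not stated whether the counts are stranded.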

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

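All tests in this part were chosen after the result was seen, except the count of other splits of the samples.

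The first pattern is that B lineage genes were higher, and Cd34 and other genes lower, in hCD25 than in BLP. If the 8 libraries are taken as exchangeable, chance is unlikely but not excluded. Of their 56 splits 1 gave as many as the real 51 genes, the real split itself, which is the smallest share possible, and the highest other gave 1. The splits ignore naming style, with which as a term the count was 1, and the shared number of hCD25 4 and 5, which when summed gave 32. Every other split also mixes libraries with and without Y-linked transcripts, so the low counts there do not single out the population as the cause. A minority of B lineage cells added to BLP-like cells would leave other genes above 0.5 of their BLP level. Yet 7 genes outside X and Y, among them Cd34 (-2.90 ± 0.33), fell beyond 1 on the log2 scale in a threshold test over all 17179 genes. This argues against such cells as the whole cause only where the falls come from neither the batch nor the sex weighed next. Gbp4 and Gbp6 are among the 7, and a strain variant stays open for them in the second pattern. A batch by naming style could contribute and cannot be told apart, because BLP 3 is the only BLP library of the second style: over it, hCD25 was higher by a median log2 of 2.34 (quartiles 1.67 to 3.89), in 24 of 24 B lineage genes. The sex of the mice cannot be told apart either, since each hCD25 library had 95.2 CPM or more of 4 Y-linked genes against at most 0.528 CPM in the others, and the biological difference named by the gates, hCD25 with no criterion for B220, is open and untested.

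The second pattern concerns the 5 Gbp genes of chromosome 5, of which Gbp4, Gbp6 and Gbp11 fell against ALP and these and Gbp9 against BLP, with a median log2 of -3.45, each gene taken as the mean of both comparisons. The call of Gbp11 held in 3 of 10 fits that left out 1 library against ALP and in 2 against BLP. That of Gbp9 held in 2, and with style as a term no Gbp gene was called. The family of 9 Gbp genes was at an adjusted p of 0.000164 against ALP and 0.00151 against BLP by camera with the preset correlation, and at adjusted p = 0.973 and 0.974 with an estimated correlation. A lower interferon response as a whole would lower its other genes alike, but the 16 genes of that list had a median of -0.404 (quartiles -1.61 to -0.0944). The list leaned the same way, with 3 of 16 members positive in each comparison. Camera with the preset correlation gave adjusted p of 0.0565 against ALP and 0.126 against BLP. An equal fall of all these genes is argued against, and a partial one stays open. Reads shared between copies would leave the summed CPM of the family unchanged, but the sum fell by 2.36 on the log2 scale, to at most 158 CPM in hCD25 against at least 536.8 CPM elsewhere. A strain variant or a linked region may be involved and stays open: the 4 Gbp genes of chromosome 3 had a median of -0.492, but the exact permutation test of medians, two-sided, gave p = 0.0714. The chromosome 5 members were at -2.49 or lower against ALP and -3.28 or lower against BLP. Those of chromosome 3 were at -1.55 or higher and -1.09 or higher. Of 97 other tested genes within 5 Mb 0 were called, where 67 and 51 of all 17179 genes were called, so this says little about linkage. A style batch stays open too, because the median difference of -4.14 to BLP 3 rests on 1 library.

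The third pattern is a rise of mt-Nd3, a fall of mt-Nd6 and a positive median log2 of 79 ribosomal protein genes in hCD25 against ALP. No ribosomal protein gene was called higher, and the symbol families Rps and Rpl passed camera only with the preset correlation, at 9.84e-19 and 4.87e-13, with adjusted p = 0.973 for each with an estimated correlation. A batch by naming style could account for mt-Nd6, since BLP 3 differed from BLP 1 and 2 by 1.09 times the difference between hCD25 and ALP. It could also account for the shift of the ribosomal protein genes, at a median log2 of 0.426 (quartiles 0.0325 to 1.09) between BLP 3 and BLP 1 and 2, against 0.615 between hCD25 and ALP. For mt-Nd3 the same ratio was 0.39, which leaves the batch open, and no biological explanation was tested. Gm28438, an unprocessed pseudogene of chromosome 1, was called beside mt-Nd3. Its log2 was 5.725 against ALP and 4.18 against BLP, where mt-Nd3 was at 6.00 and 4.26. Whether the 2 share reads was not tested.

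Of 66 values, those of genes and library measures, compared among the 5 hCD25 libraries, 5 had a library far from the other 4, where chance gives about 1 in 20. Mpo was at 407.2 CPM in hCD25 3 and at 46.8 to 92.1 CPM in the others, and hCD25 3 also held the highest neutrophil sum, 1240 CPM. Il2ra was at 15.6 CPM in hCD25 5 and at most 2.72 CPM in the others. Ly6d was at 248.3 CPM in hCD25 2 and at 139.7 to 164.4 CPM in the others. Clu was at 0.1771 CPM in hCD25 4 and Epha7 at 0.1698 CPM in hCD25 2, each at 0 in the others. They rest on 1 and 2 counts, and any count against 4 libraries with 0 meets the rule, which leaves 3 values, where 3.3 of the 66 are expected by chance.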

How the results depend on the processing

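The alternatives without genes on X and Y, with the style term but without BLP 2, and with robust estimation were chosen after seeing the data, and the rest were planned. The B lineage list stayed higher and past the threshold in each comparison under every alternative run for it. No list test was run with DESeq2, limma-voom, robust estimation or only the populations compared. None was run within 1 style, with hCD25 libraries summed or without genes on X and Y. Apart from fry and an estimated correlation, camera used the preset 0.01. The estimate for the B lineage list was 0.0754. Its adjusted p was then 0.0234 for BLP against ALP, 0.00176 for hCD25 against ALP and 0.0147 for hCD25 against BLP. That estimate was not used when libraries were left out. Leaving out each library gave adjusted p from 5.93e-30 to 3.44e-06 for BLP against ALP, 9.86e-35 to 5.88e-27 for hCD25 against ALP and 2.27e-28 to 1.51e-09 for hCD25 against BLP. The T lineage list passed no directional test that was run. Fry's mixed test, which counts changes in both directions, gave it adjusted p of 0.000165 for hCD25 against ALP and 0.00301 for hCD25 against BLP. The direction of the list for hCD25 against ALP turned at adjusted p of 0.926 with no count filter, 0.961 without ALP 1 and 0.900 without BLP 3, and leaving out libraries gave 0.450 to 0.967 there, 0.126 to 0.755 for BLP against ALP and 0.132 to 0.482 for hCD25 against BLP.

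Counts of genes are given in the order BLP against ALP, hCD25 against ALP, hCD25 against BLP, beside 8, 67 and 51. They were 65, 1130 and 785 by DESeq2, which called many unchanged genes in the simulation with estimated dispersions. They were 11, 4019 and 472 by limma-voom, which called 1, 0 and 1 unchanged genes in that simulation. The simulation, which had no batch, therefore does not account for 4019 genes beside 67. No count filter gave 24, 452 and 480, and a fit of only the 2 populations compared gave 0, 1265 and 34. They were 8, 10 and 1 with style as a term, and 16, 20 and 10 with that term but without BLP 2. Within 1 style the first was 0 and the last 11, with the spread of hCD25 alone in the latter, and hCD25 against ALP had no value. Summing hCD25 4 and 5 gave 8, 45 and 32. Leaving out each library gave 1 to 22, 14 to 799 and 26 to 1308. RLE factors gave 8, 62 and 44, the stricter filter 8, 73 and 50, robust estimation 8, 67 and 56, and leaving out X and Y 8, 56 and 40. Where ALP or BLP was left with 1 library, that library was assumed to vary like the other groups. BLP libraries do not enter the means of hCD25 and ALP. The rise from 67 to 1265 without BLP, and to 799 without BLP 2, therefore came through the shared spread, scaling and filter. The count of 67 thus depends on the BLP libraries fitted beside it. Which of these weighed most, and the causes of the other changes, were not tested.

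The replicate number as a block gave 6, 20 and 12 genes. The numbers do not pair the samples: correlations of library deviations between populations lay between -0.059 and 0.0553 across genes, so the block mainly spends degrees of freedom.

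For named genes that passed, directions held in each alternative except mt-Nd6, hCD25 against ALP, at 0.13 with style as a term. The CPM ranges of the populations compared did not overlap for any gene that passed, so leaving out a library could hardly turn these. Among those that did not pass, the log2 value of BLP against ALP turned for Flt3, at -0.013 by limma-voom and -0.073 with the style term without BLP 2, and for Mpo, at -0.20 by limma-voom, -0.095 with the replicate block and -0.36 with the style term without BLP 2. For hCD25 against ALP, Kit was at 0.30 and Il2ra at -0.23 with style as a term, and Il2ra at -2.78 with that term without BLP 2. For hCD25 against BLP, Kit was at 0.3594 with style as a term, 0.3631 within the second style and 0.3586 with the term without BLP 2.

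Leaving out 1 library also turned some genes that did not pass. For BLP against ALP the log2 values ran from -0.055 without BLP 2 to 0.51 for Flt3, from -0.27 without BLP 2 to 0.58 for Mpo, which was at -0.058 without ALP 1, from -0.0185 without BLP 2 to 0.50 for Myc, and from -3.94 to 3.85 without ALP 1 for Il2ra. Il7r, hCD25 against ALP, ran from -0.025 without ALP 2 to 0.32, and Hlf, hCD25 against BLP, from -1.59 to 0.24 without BLP 1. Depth limits what 0 counts show, since 3 counts stand for up to 0.62 CPM in 1 library.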

Other observations

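Genes in this part were chosen after their values were seen. Cd27 and Cd44, both surface receptors of lymphoid cells, fell in hCD25. Cd27 was at 269.9 ± 0.0277 CPM (SD, n = 2) in ALP, 247 ± 43.7 CPM (SD, n = 3) in BLP and 63.96 ± 19.97 CPM (SD, n = 5) in hCD25, with a log2 of -1.95 ± 0.30 against BLP (edgeR adjusted p = 0.013). Cd44 was at 286 ± 44.2, 245 ± 7.45 and 98.6 ± 16.7 CPM, with a log2 of -1.31 ± 0.25 against BLP (edgeR adjusted p = 0.0428). Against BLP the call of Cd44 held in 2 of 10 fits that left out 1 library, with a log2 of -1.32 (adjusted p = 0.109) without ALP 1 and -1.17 (0.130) without hCD25 1, and that of Cd27 in 8, with -1.86 (0.0655) without hCD25 1 and -1.88 (0.0637) without hCD25 5. The log2 difference to BLP 3, the only BLP library of the second naming style, was -1.30 for Cd44 and -1.63 for Cd27. Chchd10, which encodes a mitochondrial protein, rose from 4.05 ± 1.07 CPM in ALP and 18.2 ± 7.25 CPM in BLP to 182 ± 12.4 CPM in hCD25, with a log2 of 5.48 ± 0.50 against ALP and 3.32 ± 0.37 against BLP. It was past the threshold without each library in turn in both comparisons. Gimap4, of the GTPases of immunity-associated proteins, was at 94.4 ± 18.5 CPM in hCD25, 9.20 ± 8.43 CPM in BLP and 3.75 ± 1.46 CPM in ALP and did not pass (edgeR adjusted p = 0.121 against ALP and 0.143 against BLP). Mzb1, a B lineage list member, rose by a log2 of 8.58 ± 1.13 against ALP and did not pass against BLP, at 2.73 ± 0.68. Gbp8 did not pass in either comparison, at a log2 of -3.37 against ALP and -3.54 ± 0.72 against BLP.

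The genes called in the 3 comparisons overlapped. All 8 genes higher in BLP than in ALP were also among the 43 higher in hCD25 than in ALP, where 0.02 would be shared if the calls were independent, and 5 were among the 23 higher in hCD25 than in BLP. The lists higher in hCD25 against ALP and against BLP shared 22 genes and the lower lists 15. The comparisons share libraries, so these overlaps are not independent evidence.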
